A study of Arabidopsis thaliana with 19 samples.

How the data were processed

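Small RNAs of Arabidopsis thaliana (ecotype Columbia) were measured in immature flower buds of stages 1 to 12 from plants grown in 16-h days at 22 °C. Per the labels' protocols, small RNA was isolated with TRIzol and concentrated with a microRNA column kit, or recovered from AGO1 immunoprecipitates (AGO1-IP) and mock immunoprecipitates (mock-IP). Libraries were made with the TruSeq Small RNA kit and sequenced on HiSeq instruments. The labels do not tie a library to an instrument. Tables of 17 libraries in 12 groups were analysed. They comprise 9 libraries of total small RNA (wild type, 7 mutant genotypes, with rdr1/rdr2/rdr6 in 2 libraries) and 8 immunoprecipitation libraries (AGO1-IP and mock-IP, wild type and pol IV, 2 each). A further 2 methylC-seq samples were not analysed here. Groups were taken from the sample titles. The labels do not say that replicates came from separate plants, so p-values measure the spread between these libraries, which may be technical.

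Each table lists distinct sequence tags and, per the deposited file names and values, a read abundance scaled to a library total (RPM) by the authors. The genome build was TAIR 10, per the submitters' processing notes. The aligner, the filters and the read total behind the RPM scale are not given in the sources used here. The RPM columns deposited by the authors are whole multiples of the value of 1 read in each library. Divided by that value, 100% of the values were whole within 0.01 reads or, for large values, within a relative 2e-05. This gave between 203900 reads of 18 to 28 nt (mock-IP pol IV A) and 22465488 (AGO1-IP pol IV A). The read totals implied by the scale ran from 1512294 to 31276689. The deposited RPM of 18 to 28 nt sums to between 134828 in mock-IP pol IV A and 901336 in AGO1-IP pol IV B. What sets this difference between libraries is not given. Over all lengths total dcl4 sums to 1.016e+06 RPM, with 12791667 reads against an implied total of 12589791.

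The total pol IV and total dcl4 tables were made differently from the other 15. They hold tags of 15 to 49 and 15 to 48 nt, whereas the others hold 18 to 28 nt. Of their 18- to 28-nt RPM, 41.5% and 31.4% lay in tags absent from each of the other 15 tables, with 2670 and 1541 such tags of at least 10 RPM. Each of the 15 other tables had at most 4 such tags when set against the remaining 14. Their share of RPM in absent tags ran from 0.719% (AGO1-IP pol IV B) to 21.9% (AGO1-IP wild type B). It was 10.6% in total wild type. Tags that extend a listed miRNA by 1 base at its end were also counted. Among listed sequences of at least 100 RPM, 3 or 4 of the 4 possible extensions were present for 17 of 22 in total pol IV and for 17 of 18 in total dcl4. In 14 of the other tables this was so for 0 sequences, and in AGO1-IP pol IV A for 1 of 29. A higher value in these 2 libraries than in wild type can thus stand for a tag that the wild-type table leaves out, so their higher tags were also counted among tags present in another table. The wider RPM content of the 2 tables may also change their scale against the others. All values used tags of 18 to 28 nt. Transcripts of the mutated genes are not measured by these tables, so the genotypes are as labelled.

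No genome sequence was used here, so tags were the features. The tests planned on windows and on genes, before the data were examined, became 1 test on 21- to 22-nt tags. The planned lists of loci (tasiRNA loci, phasiRNA-forming PPR, auxin receptor and NB-LRR genes, transcription factor targets, small RNA machinery, genes silenced by RNA-directed DNA methylation) could not be placed on tags. For the miRNA lists and the tasiRNAs, 46 mature sequences, recalled from general knowledge, were matched by identity. The families were fixed before the data were examined and the sequences were written after. Of these, 45 were found in at least 1 library, and 40 of the 44 miRNAs have 21 to 22 nt. No genomic position is given for any tag.

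Pol IV neighbourhoods took the place of Pol IV windows. A tag belonged to one when its best shared 18-nt stretch carried at least 5 RPM of 23- to 24-nt tags in the total wild-type library and a log2(RPM + 1) lower by 2 or more in total pol IV. The 21- to 22-nt tags and the immunoprecipitation libraries did not enter this rule, but the low 23- to 24-nt value of total pol IV holds by construction. The neighbourhoods held 61.5% of wild-type 23- to 24-nt abundance and 63860 distinct 21- to 22-nt tags of wild type. As an additional list, chosen after seeing the data, 53 tags of at least 10 RPM in wild type were at least 4-fold lower in rdr1/rdr2/rdr6, dcl2/dcl4 and dcl4 but within 2-fold of wild type in pol IV. These are called RDR- and DCL4-dependent tags. Tags that share 18 nt with a listed miRNA were a further list.

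The immunoprecipitation test was limma with a trend, without robust fitting, on log2(RPM + 1). It used 4115 tags with a mean of at least 1 RPM over the 8 libraries, and the 4 groups shared 1 estimate of the spread. The trend also draws the spread of each tag toward that of tags of like abundance. A limma p therefore does not rest on the tag's own libraries alone. A log2 difference on this scale understates the change of tags with low abundance. Benjamini-Hochberg adjusted p under 0.05 counted as a call. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and with fry, adjusted over the lists. Here fry tests whether members move one way on balance. Compositions and sums over neighbourhoods were compared with two-sided exact permutation tests, where 2 against 2 libraries cannot give a p below 0.333. Total libraries were compared with wild type without a test, since each genotype except rdr1/rdr2/rdr6 (2 libraries) has 1 library. Their values are descriptions of these libraries. For a list in total small RNA, the percentile of its median was taken among 10000 random lists of the same size matched on mean abundance. Intervals are 95% exact (Clopper-Pearson for shares, Poisson for sums) and cover counting error only, since PCR reads are not independent molecules.

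On simulated data for AGO1-IP pol IV against wild type, the limma test recovered 88% of 4-fold and 100% of 16-fold changes at a dispersion of 0.05 (3583 tags), with 5 of 193 calls on unchanged tags. At a dispersion of 0.4 (3450 tags) it recovered 11% and 68%, with 21 of 100 calls on unchanged tags, more than the threshold of 0.05 allows. Calls therefore depend on how alike the replicates are. The simulated wild-type AGO1-IP libraries shared 1 mean per tag, whereas the observed A and B correlated at r = 0.173 across tested tags. The simulation thus does not cover their spread.

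The rule for named tags, fixed before the data were examined, was the 10 called tags with the largest difference in each direction whose libraries do not overlap, then list members. With no call, it was the 10 with the smallest p. In total libraries it was the 10 largest differences in each direction among tags of at least 10 RPM. Counts of 4-fold lower or higher tags and list members there are also on the log2(RPM + 1) scale, so a ratio of RPM just above 4 can fall short of them. The text gives the top of each ranking. Alternatives were other pseudocounts, filters, scalings (to the summed listed 21- to 22-nt miRNA tags, or TMM), edgeR quasi-likelihood and DESeq2 tests on the recovered whole reads, the replicate letter as a block, 21 nt or 22 nt alone, each library left out, and other settings of the neighbourhood rule. Replicates were compared by chi-square on tags of at least 20 reads. No pair agreed within sampling noise, so none was merged. The ratio of chi-square to degrees of freedom was at least 19.4 between replicates. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.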

Results

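Small RNAs were sequenced from Arabidopsis flower buds to ask whether RNA polymerase IV (Pol IV), which makes the precursors of 24-nt siRNAs, also gives rise to 21- to 22-nt small RNAs, which proteins these need, and whether they enter ARGONAUTE1 (AGO1), the main effector of miRNAs. Total small RNA came from wild type (4816289 reads of 18 to 28 nt) and from mutants of DICER-LIKE proteins (dcl), which release small RNAs from double-stranded precursors. It also came from mutants of RNA-dependent RNA polymerases (rdr), which make the second strand, and from the Pol IV mutant. There was 1 library each of wild type, dcl1 (6749677 reads), dcl4 (7134952), dcl2/dcl4 (8060614), dcl2/dcl3/dcl4 (1353793), rdr1 (2874077) and pol IV (2677576), and 2 of rdr1/rdr2/rdr6 (1001044 and 1317859). AGO1-IP and mock-IP libraries came from wild type and pol IV, 2 each. Their reads were 6343301 and 1085531 for AGO1-IP wild type A and B, 313000 and 860308 for mock-IP wild type, 22465488 and 7404389 for AGO1-IP pol IV, and 203900 and 389544 for mock-IP pol IV. Differences between total libraries have no replicate check, except that the 2 rdr1/rdr2/rdr6 libraries can be set side by side.

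The 24-nt class dominated total small RNA of wild type, with 56.4% of 18- to 28-nt abundance, against 20.9% at 21 nt and 5.94% at 22 nt. It made up 7.62% in pol IV, 5.18% and 5.35% in the 2 rdr1/rdr2/rdr6 libraries and 6.74% in dcl2/dcl3/dcl4. It stood at 63.3% in dcl1, 62.5% in dcl2/dcl4, 60.2% in rdr1 and 45.1% in dcl4. At 21 nt the share was 36.9% in pol IV, 64.7% and 61.3% in rdr1/rdr2/rdr6, 45.1% in dcl2/dcl3/dcl4, 15.1% in dcl2/dcl4 and 10.3% in dcl1. These are shares of each library, so a loss of 24-nt tags raises every other class.

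**Figure D1:**
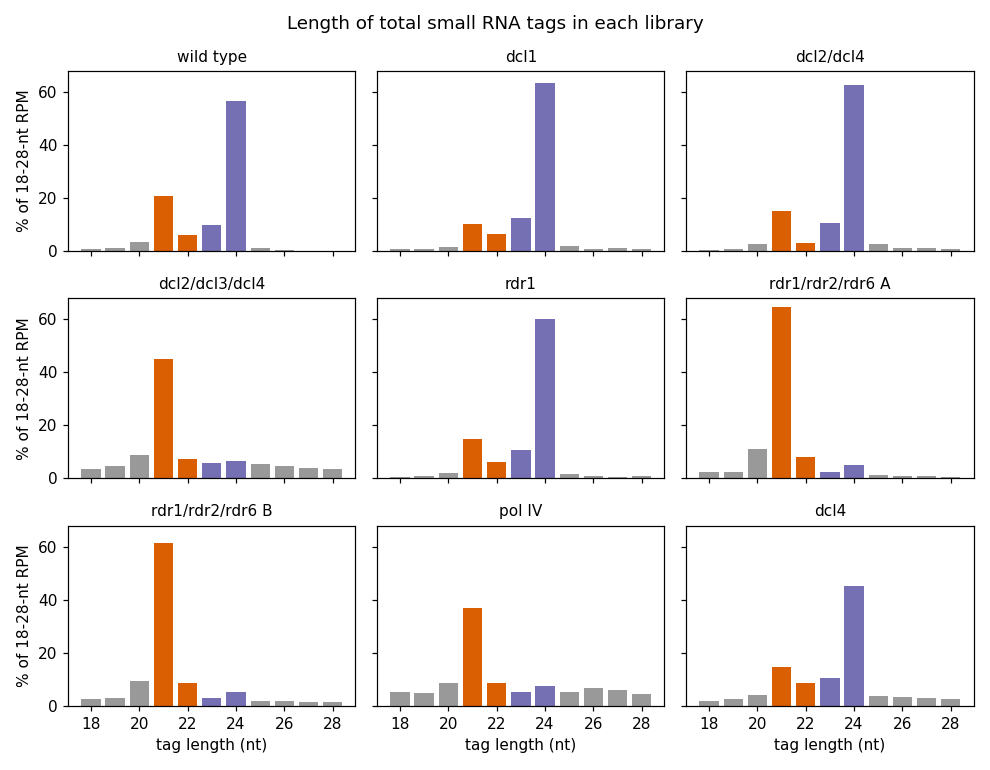
Share of 18- to 28-nt RPM (vertical axis, %) at each tag length (horizontal axis, nt) in each total small RNA library, with 21 to 22 nt and 23 to 24 nt in separate colours. The 24-nt bar stands at 56.4% in wild type and between 5.18% and 7.62% in rdr1/rdr2/rdr6, dcl2/dcl3/dcl4 and pol IV.

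Tags of 21 to 22 nt from Pol IV neighbourhoods, sequences that also give Pol IV-dependent 23- to 24-nt tags, summed to 30996 RPM in wild type and made up 13.6% of its 21- to 22-nt abundance. They were close to lost without Pol IV, at 1.95% of wild type in pol IV (95% interval 1.88 to 2.02), and without the 3 polymerases, at 2.07% ± 0.860 (SD, n = 2) in rdr1/rdr2/rdr6. In rdr1 76.0% remained (75.6 to 76.5), beside 77.0% of the 23- to 24-nt tags. At 22 nt alone the values were 107% in dcl1, 76.7% in rdr1 and 54.2% in dcl4, against 26.2% in dcl2/dcl4 and 21.8% in dcl2/dcl3/dcl4. The 1.95% of pol IV at 21 to 22 nt was not set by the rule that chose the neighbourhoods, whereas its 0.913% at 23 to 24 nt was.

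Among the DICER-LIKE mutants, dcl2/dcl4 kept 28.8% of the 21- to 22-nt abundance (28.6 to 28.96) and 88.4% of the 23- to 24-nt abundance. In dcl1 the values were 92.0% and 88.8%. In dcl4 they were 46.7% and 44.8%, and its 21- to 22-nt abundance per 100 of 23 to 24 nt was 9.35, beside 8.98 in wild type, 9.31 in dcl1 and 2.92 in dcl2/dcl4. Scaled to the listed miRNAs, dcl4 stood at 118% of wild type in place of 46.7%, and rdr1 at 166% in place of 76.0%, so that direction depends on the scale. In dcl2/dcl3/dcl4 23- to 24-nt tags stood at 2.75% of wild type, 22-nt tags at 21.8%, and 21-nt tags stood at 141% (140 to 142), or 160% when scaled to the listed miRNAs. The ratio of 22 to 21 nt was 1.76 in wild type, 2.87 in dcl1, 2.85 in dcl4, 1.38 in dcl2/dcl4 and 0.272 in dcl2/dcl3/dcl4.

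**Figure D2:**
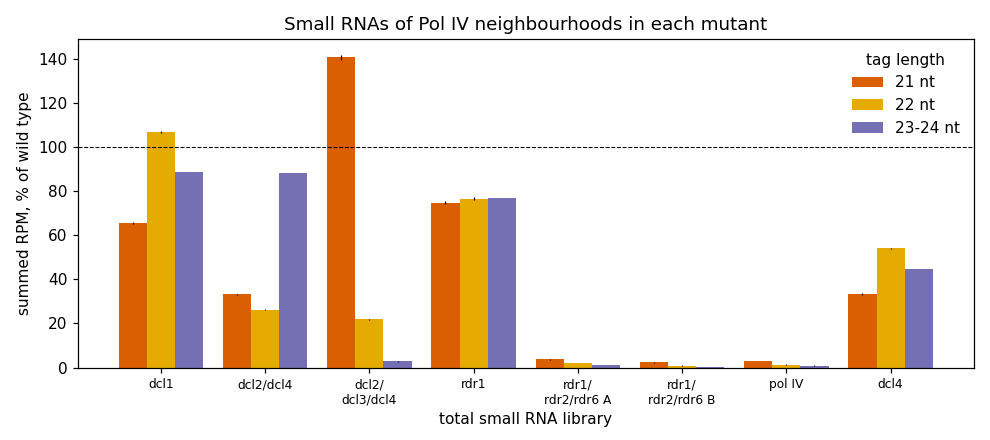
Summed RPM in Pol IV neighbourhoods as percent of the wild-type library (vertical axis) for each mutant library (horizontal axis), in separate bars for 21, 22 and 23 to 24 nt, with 95% Poisson intervals from read counts. In dcl2/dcl4 the 22-nt bar stands at 26.2% beside 88.4% at 23 to 24 nt, and in dcl2/dcl3/dcl4 the 21-nt bar stands at 141%.

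Listed miRNAs were lower in dcl1, and tasiRNAs (trans-acting siRNAs, made by RDR6 and DCL4 after miRNA cleavage) in the dcl4 mutants, rdr1/rdr2/rdr6 and dcl1. As deposited, tasiRNAs were also lower in rdr1, where the listed miRNAs were lower too. In dcl1, which lacks full activity of the enzyme that makes most miRNAs, 16 of 21 measured conserved miRNAs were at least 4-fold lower than in wild type, with a median log2 difference of −3.20 (percentile 0 among random lists). Examples are miR158 at 132 RPM against 14915, miR161.1 at 7.74 against 739 and miR159b at 147 against 5359. miR168, which targets AGO1 mRNA, stood at 1307 RPM in dcl1 against 966. In dcl4, dcl2/dcl4, dcl2/dcl3/dcl4 and rdr1/rdr2/rdr6, TAS3 tasiR-ARF, which targets auxin response factors, was at most 0.453 RPM against 43.6 in wild type, while pol IV had 69.3. TAS1 siR255 was listed at 10.6 RPM in wild type and 14.3 in pol IV, and at no more than 0.101 in those 5 libraries and 0 in dcl1, where tasiR-ARF had 22.6. In rdr1 tasiR-ARF had 10.7 RPM and siR255 2.36. The listed 21- to 22-nt miRNAs summed to 60421 RPM there against 131873 in wild type, so these values depend in part on the scale. miR839, listed as dependent on DCL4, had 86.9 RPM in wild type and 143 in dcl1, against 0.159 in dcl4, 0.571 in dcl2/dcl3/dcl4 and 0 in dcl2/dcl4, where 3 reads would be 0.302 RPM. Of the other lists, the 22-nt trigger miRNAs had 1 of 1 measured member at least 4-fold lower in dcl1 and 0 of 3 in pol IV. For miR845, the measured pollen-enriched miRNA, levels were 12.3 RPM in wild type, 0.703 in dcl1 and 13.3 in pol IV.

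The number of conserved miRNAs at least 4-fold apart from wild type differed among the remaining mutants. Of 26 measured in pol IV, 0 were at least 4-fold lower and 1 was higher (median log2 0.64, percentile 89.5), in dcl2/dcl4 0 of 24 were lower and 1 higher, and in dcl2/dcl3/dcl4 0 of 24 were lower or higher. In rdr1, 5 of 22 were lower (median −1.22, percentile 1.11). In dcl4, 0 of 21 were lower, with a median of −0.84. In rdr1/rdr2/rdr6 A and B, medians were 1.52 and 1.71, with 4 and 7 of 26 higher. The nutrient-responsive miRNAs, which respond to copper, phosphate or sulfate supply, had 2 of 4 measured members at least 4-fold lower in pol IV (median −1.68, percentile 0.01) and in dcl2/dcl4 (median −2.80, percentile 0.81). Both times these were the copper-responsive miR398b and miR408. In dcl1 4 of 4 were lower (median −4.63, percentile 0.47), in dcl2/dcl3/dcl4 0 of 4 (median −1.53) and in dcl4 0 of 5 (median 0.90). miR398b stood at 890 RPM in wild type, 112 in pol IV, 23.8 in dcl2/dcl4 and 2658 in dcl4, and miR408 at 144, 19.5, 5.23 and 269.9.

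Across single tags, wild type had 596 tags of 21 to 22 nt with at least 10 RPM, of which 191 lay in Pol IV neighbourhoods and 69 shared 18 nt with a listed miRNA. At least 4-fold lower were 207 in pol IV, including 191 of the 191 in neighbourhoods, and 274 and 277 in the 2 rdr1/rdr2/rdr6 libraries, again with 191 of 191. In dcl2/dcl4 325 were lower (136 in neighbourhoods), in dcl2/dcl3/dcl4 306 (127), in dcl1 243 (37, with 49 of the 69 miRNA-sharing tags), in dcl4 189 (72) and in rdr1 134 (33). Scaled to the listed miRNAs, the counts became 90 in dcl4, 40 in rdr1 and 157 in dcl1, where most of the miRNAs behind that scale are themselves lower. The tag TTCTAAGTTCAACATATCGAC was among the 4 lowest in 6 libraries. It had 783 RPM in wild type, 2.82 in dcl2/dcl4, 2.00 in dcl2/dcl3/dcl4, 5.89 and 1.05 in rdr1/rdr2/rdr6, 3.73 in dcl4 and 2.81 in dcl1. In dcl2/dcl4 the lowest was TGACGAGAGAACTTATTGGCCT, at 1.51 against 615 RPM. In pol IV it was AGAATACCGGAACTCTTGGCCG, a neighbourhood tag, at 1.81 against 197. In dcl1 the lowest was TTGACAGAAGAGAGTGAGCAC, which shares 18 nt with a listed miRNA, at 1.76 against 622. In rdr1 it was TGAATGATGCCTGGCTCGAGA, listed at 0 against 50.1 RPM, where 3 reads would be 0.643 RPM.

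Higher tags, with at least 10 RPM in the mutant, numbered 369 in dcl2/dcl3/dcl4, 183 and 311 in rdr1/rdr2/rdr6, 98 in dcl1, 91 in dcl2/dcl4 and 45 in rdr1. Scaled to the listed miRNAs they numbered 440 in dcl2/dcl3/dcl4, 37 and 115 in rdr1/rdr2/rdr6, 548 in dcl1, 192 in dcl2/dcl4 and 331 in rdr1. The highest in dcl2/dcl3/dcl4 was CTTGCACATGGGTTAGTCGATC, at 1044 RPM against 4.40. In dcl1 it was TTCCGAACCCGTCGGCTGTCAG, at 116 against 0.176, which in wild type is 1 read. Tags of rRNA, tRNA, snRNA and snoRNA were not removed, since that needs a genome, so higher tags can include their fragments. For pol IV and dcl4, 794 and 444 tags were higher, but 232 and 144 of them were present in another table, and scaled to the listed miRNAs 737 and 1327 were higher. These counts compare differently filtered tables.

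AGO1-IP was compared with mock-IP to define what AGO1 holds, which is known to prefer small RNAs of 21 to 22 nt that begin with U (T in the tags). In pol IV, 98.0% ± 0.0202 (SD, n = 2) of 21- to 22-nt abundance began with T in AGO1-IP against 59.6% ± 6.24 in mock-IP, and 21 to 22 nt made up 83.2% ± 2.05 against 19.3% ± 2.12. In wild type the 2 AGO1-IP libraries differed. In A 92.0% began with T, and in B 30.9% (95% interval 30.7 to 31.0), below the mock-IP values of 47.7% and 35.1%. The share of 21 to 22 nt was 64.6% in A and 29.9% in B, against 28.6% and 26.5% in mock-IP. The group means were 61.4% ± 43.2 against 41.4% ± 8.92 for T, where the libraries overlapped (exact permutation p = 1), and 47.2% ± 24.6 against 27.5% ± 1.55 for size. For size both AGO1-IP libraries lay above both mock-IP libraries, with an exact permutation p = 0.33, the smallest possible with 2 against 2. Over the 4115 tested tags, AGO1-IP wild type B correlated with mock-IP wild type B at r = 0.917 and with AGO1-IP wild type A at 0.173 (across tags, which are not independent). Without AGO1-IP wild type A, the T share of AGO1-IP minus that of mock-IP was −10.5 percentage points. Every wild-type AGO1-IP mean below carries the difference between A and B.

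**Figure D3:**
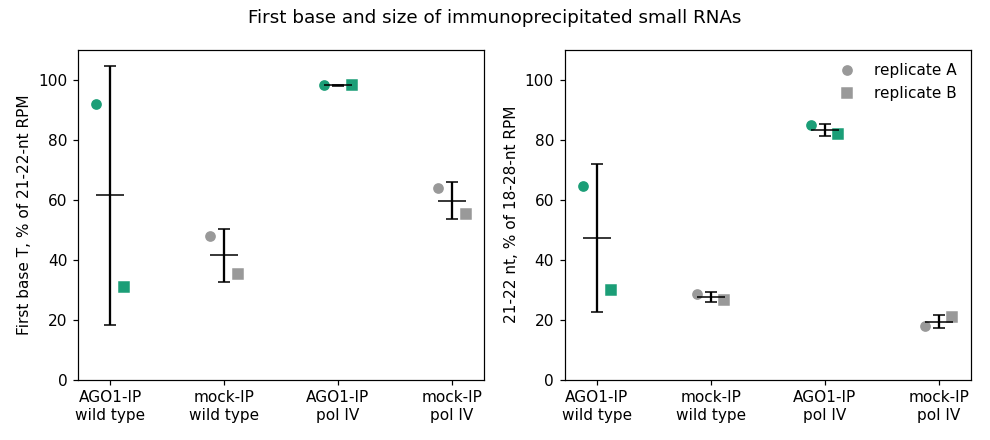
Percent of 21- to 22-nt abundance that begins with T, and percent of 18- to 28-nt abundance that is 21 to 22 nt (vertical axes), in the 8 immunoprecipitation libraries by group (horizontal axis), with 1 symbol per library and bars for the mean ± SD. AGO1-IP wild type A and both AGO1-IP pol IV libraries lie at 92.0% to 98.0% T, while AGO1-IP wild type B lies at 30.9%, below both wild-type mock-IP libraries.

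In AGO1-IP, Pol IV neighbourhood tags of 21 to 22 nt were 74.7-fold less abundant in pol IV than in wild type (465 ± 148 RPM against 34733 ± 16368, SD, n = 2; exact permutation p = 0.33, the smallest possible). Of the 1035 tested neighbourhood tags, 1024 had a lower mean in pol IV, with a median log2 difference of −2.08. These tags are near absent in pol IV and passed the filter mainly through the wild-type libraries. Their lower mean, and the list tests that follow, were thus largely fixed in advance. By camera this list was lower than other tags (adjusted p = 2.71e-211, and 0.0400 with an estimated correlation), while fry gave an adjusted p of 0.222. The loss was not particular to the AGO1 fraction: in mock-IP they were 47.3-fold less abundant in pol IV than in wild type, and 25.4-fold without mock-IP wild type B or 69.2-fold without A. By limma 15 tags were called lower in pol IV, and 15 of the 15 lie in neighbourhoods. The lowest were CGAGAAAACCTAGAACTTCCCT (log2 −5.80, adjusted p = 0.0455, 0.186 ± 0.0817 RPM against 244.6 in wild type A and 16.7 in B), TTTCGGAACAACTCAAAAGCCT (−5.67), TAGAAGTCCAATTGTAGCAGCT (−5.49) and TCTGAATTCTACTCTTGGCAAG (−5.31), each with the same adjusted p. Within the neighbourhood list alone, 290 tags passed when adjusted over the list alone. Without AGO1-IP wild type B, 1017 tags were called lower, 853 of them in neighbourhoods, and the median was −3.33. The list then had an adjusted p of 0.148 by camera with an estimated correlation, and of 0.00457 by fry.

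A further 4 tags were called higher in AGO1-IP of pol IV. They were miR166, which targets HD-ZIP III transcription factors (log2 3.84, SE 0.742, limma adjusted p = 0.000931; 321907 ± 4374 against 69659 ± 93252 RPM), the overlapping tags TTTAGGTCGAGCTTCATTGGA (5.87, SE 1.43, adjusted p = 0.0455; 96.1 ± 7.94 against 0.868 ± 1.23) and TTAGGTCGAGCTTCATTGGAA (4.56, adjusted p = 0.0245; 24.6 ± 8.73 against 0.0579 ± 0.0818), and TTTCCGTCAGAAGTTTCCTCGA (limma adjusted p = 0.0455; 14.0 ± 4.07 RPM, listed at 0 in both wild-type libraries). For miR166 the wild-type SD exceeded the wild-type mean. Its SE of 0.742 thus rests largely on the trend over tags of like abundance. Its p does not measure the gap between its own 2 wild-type libraries. The other 3 remained near 0 also in AGO1-IP wild type A, which had 1.74, 0.116 and 0 RPM. Conserved miRNAs had a higher mean in 23 of 23 cases (median 3.29), with 1 called among all tags and 2 adjusted over the list alone. The camera call (adjusted p = 6.60e-07) was lost with an estimated correlation (adjusted p = 0.465). For miR165 the values were 73412 ± 19458 against 11254 ± 14828 RPM (adjusted p = 0.0564 by limma), and for miR159a 40015 ± 23567 against 16493 ± 22780. Nutrient-responsive miRNAs (7 of 7 higher, median 2.63) had adjusted p = 0.0153, and 0.465 with an estimated correlation, with 0 calls. The 22-nt trigger miRNAs (3 of 3 higher, median 2.92) had adjusted p = 0.104 and 0 calls. Without AGO1-IP wild type B, the median of the conserved miRNAs was 0.62 and that of the nutrient-responsive miRNAs 0.01, with 0 calls in either list. Over all tags 89 were then called higher.

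Of the 19 calls between genotypes, all 19 were of tags whose libraries do not overlap. Non-overlap held for 41.5% of the tested tags, where chance gives 33.3%. The median log2 difference of all tested tags was 0.53, and −0.88 when scaled to the listed miRNAs. No call was left by that scaling, by TMM or by edgeR (1060 tags at an unadjusted p under 0.05), whereas DESeq2 called 675, of which 672 were lower and 643 of these lie in neighbourhoods. Leaving out either AGO1-IP pol IV library gave 0 calls, mock-IP wild type A or either mock-IP pol IV library 1, mock-IP wild type B 29, AGO1-IP wild type A 2126, of which 1825 were higher, and AGO1-IP wild type B 1106, of which 89 were higher. With the replicate letter as a block, 1 call was left, and the neighbourhood list had adjusted p = 0.0942 by camera with an estimated correlation.

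AGO1-IP against mock-IP in wild type asked whether Pol IV neighbourhood tags are held by AGO1. The summed 21- to 22-nt abundance was 2.80-fold higher in AGO1-IP (34733 ± 16368 against 12397 ± 8104 RPM, exact permutation p = 0.33, the smallest possible), with 46307 RPM in A and 23159 in B against 6667 and 18127 in mock-IP. Scaled to the listed miRNAs the direction turned, to a log2 of −0.055. Those miRNAs summed to 257967 RPM in AGO1-IP A and 5889 in B, against 12756 and 4834 in mock-IP. That scale thus divides out enrichment that AGO1 itself gives in A, and shows only enrichment beyond that of miRNAs. Its factors were 0.511 for A and 22.4 for B, so B weighs far more in that mean. The share of neighbourhood tags beginning with T was 27.3% in total wild type, 75.5% in AGO1-IP A and 20.4% in AGO1-IP B, against 15.5% and 23.2% in mock-IP. No tag was called by limma, edgeR or the replicate block (243, 431 and 124 at an unadjusted p under 0.05), and 153 were called by DESeq2, each higher in AGO1-IP and 29 of them sharing 18 nt with a listed miRNA. The smallest p were those of TCTTGGCAGAAACTTTGATCAG (57.0 ± 77.3 against 1.04 ± 1.47 RPM, limma adjusted p = 0.462) and TAGAAGTCCAATTGTAGCAGC (60.1 ± 81.6 against 1.498 ± 2.12), both neighbourhood tags, and of miR166 (69659 ± 93252 against 5914 ± 4428). Conserved miRNAs had a higher mean in AGO1-IP for 22 of 23 (median 2.38, 0 called, also adjusted over the list alone, camera adjusted p = 0.162), nutrient-responsive miRNAs for 7 of 7 (median 1.82) and 22-nt trigger miRNAs for 3 of 3 (median 2.58). The neighbourhood list had a median of 1.54 (camera adjusted p = 1.28e-08, and 0.935 with an estimated correlation).

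These values rest on AGO1-IP wild type B. Without it, AGO1-IP wild type was the single library A. The median log2 difference from mock-IP was then 2.49 over all 4296 tested tags. It was 2.91 over 965 neighbourhood tags and 4.96 over 23 conserved miRNAs. The neighbourhood median thus lay near that of all tags and does not by itself show that AGO1 holds them. In AGO1-IP A, miR159a stood at 32601 RPM, miR396b at 12229 and TAS3 tasiR-ARF at 199.

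In pol IV, where the AGO1-IP libraries resemble each other (r = 0.955 across tags), limma called 1026 of 4115 tags, with 1017 higher and 9 lower in AGO1-IP. Those higher include 59 of 125 tags sharing 18 nt with a listed miRNA, 30 of 51 RDR- and DCL4-dependent tags, a list chosen on the total libraries of this series, and 5 of 1035 neighbourhood tags. Most neighbourhood tags showed no difference to test in pol IV, where they are near absent. Since the 4 groups share 1 estimate of the spread, each SE and limma p here also carries the gap between AGO1-IP wild type A and B. For miR396a, A had 998 RPM and B had 3.78. Of the conserved miRNAs, 23 of 23 were higher with a median of 5.45, 15 called and 20 adjusted over the list alone. The list had a camera adjusted p = 1.17e-06, and 0.479 with an estimated correlation. The largest differences were those of miR396a, which targets growth-regulating factors (log2 7.35, SE 2.46, adjusted p = 0.0312; 1306 ± 154 against 7.86 ± 5.50 RPM), of TCTCGGTTCGCGATCCACAAG (7.08), of TTTGAACTTGTGTATTTTGAA (6.78), of TCCAATGTCTTTTCTAGTTCGT (6.67) and of miR319, which targets TCP factors (6.65; 10770 ± 1705 against 110 ± 41.1). miR390, which is known to act in AGO7, had 90.5 ± 5.56 RPM against 69.5 ± 32.8 (limma adjusted p = 1). Nutrient-responsive miRNAs had 4 of 7 called and 6 adjusted over the list alone (camera adjusted p = 0.0510), and 22-nt trigger miRNAs 2 of 3 called and 3 adjusted over the list alone (0.0566). TAS1 siR255 stood at 126 ± 28.3 against 0.661 ± 0.935 RPM (limma adjusted p = 0.0312). The lowest tag was AACGGGCTTGGCAGAATCAGC (limma log2 −3.29, adjusted p = 0.0435; 0.640 ± 0.0444 against 22.7 ± 24.6 RPM).

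Neighbourhood tags summed to 465 ± 148 RPM in AGO1-IP pol IV and 262 ± 95.8 in mock-IP pol IV, 1.77-fold apart (exact permutation p = 0.33). Of the 1035 tested ones, 254 were higher and 95 lower in AGO1-IP, and the rest showed no difference, so the median was 0. Camera placed the list below other tags (adjusted p = 5.98e-22, and 0.479 with an estimated correlation), and fry gave an adjusted p of 0.972. These tags are near absent in pol IV and passed the filter mainly through the wild-type libraries. Their rank therefore does not show exclusion from AGO1. Relative to the listed miRNAs, summed neighbourhood tags were 24.05-fold lower in AGO1-IP than in mock-IP. The 1026 calls became 0 when scaled to the listed miRNAs or tested by edgeR (749 at an unadjusted p under 0.05), 1 under TMM or the replicate block, and 696 with DESeq2, of which 552 are shared. Leaving out either AGO1-IP pol IV library gave 0 calls, either wild-type mock-IP library 2, either pol IV mock-IP library 1, and AGO1-IP wild type A and B 1994 and 2457. The median log2 difference of all tested tags was 1.59 as deposited and 0.97 under TMM, so enrichment is relative to a scale that moves with the AGO1 fraction itself.

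The difference of AGO1-IP enrichment between the genotypes, which asks whether loss of Pol IV changes what enters AGO1 beyond the change in mock-IP, gave 0 calls by limma, edgeR and DESeq2 (25, 11 and 24 at an unadjusted p under 0.05). The smallest p were those of TTAGGTCGAGCTTCATTGGAA, miR166 (log2 3.13, SE 1.05, limma adjusted p = 0.80) and TTTCCGTCAGAAGTTTCCTCGA. Neighbourhood tags had a median difference of −1.53 and conserved miRNAs of 2.77, with fry adjusted p = 0.442 for both. Without AGO1-IP wild type B the medians were −2.89 for neighbourhoods and 0.42 for conserved miRNAs. Of 965 neighbourhood tags then tested, 255 were higher and 77 lower in AGO1-IP than in mock-IP of pol IV. The rest showed no difference there, and the median was 0. The neighbourhood value therefore mostly restates the wild-type enrichment (median 2.91) with its sign turned. It cannot show whether loss of Pol IV changes the entry of these tags into AGO1 beyond mock-IP. Over all tags then tested, the median difference of enrichment was 2.26 without AGO1-IP wild type A and −0.50 without B. Its sign thus depends on which wild-type AGO1-IP library is left out.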

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

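All tests in this part that bear on an explanation were chosen after the results were seen. No group has the 4 libraries needed to test for an outlying library.

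The difference of AGO1-IP over mock-IP between the genotypes passed camera with its preset correlation for 5 lists, as medians of the log2 difference, pol IV minus wild type. It was 2.77 for conserved miRNAs (adjusted p = 5.87e-06), 2.08 for nutrient-responsive miRNAs (0.0300), −1.53 for Pol IV neighbourhoods (2.95e-76), 2.42 for RDR- and DCL4-dependent tags (0.000104) and 2.21 for tags sharing 18 nt with a listed miRNA (7.22e-10). With an estimated correlation the adjusted p were 0.478, 0.478, 0.247, 0.478 and 0.478, and fry gave 0.442 for each. Without AGO1-IP wild type B the medians were 0.42, −0.08, −2.89, −0.10 and 0.12, nearer 0 for all lists except the neighbourhoods. Most neighbourhood tags are near absent in pol IV, where their median of AGO1-IP over mock-IP was 0. Their median difference therefore follows the wild-type enrichment, 2.91 without B, with its sign turned. It is no separate sign of a change in what AGO1 holds.

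AGO1-IP wild type B lies with the mock-IP libraries. A swap with a wild-type mock-IP library would leave an AGO1-like partner there, but the highest T share of a wild-type mock-IP library was 47.7%. Mock-IP wild type B deposited again, as a plain resampling of the same reads, is also argued against, since their chi-square was 5.73 per degree of freedom. That ratio was still below those of all replicate pairs, which were at least 19.4. A second library made from the same material therefore stays open. AGO1-IP wild type A thinned to the 1085531 reads of B kept at least 91.9% T in 20 draws. Random thinning keeps shares on average, so this outcome was fixed in advance. It shows only that read depth alone does not lower the T share, and does not bear on what entered library B. An immunoprecipitation that recovered little AGO1 and a wrong label cannot be told apart, because both predict the 30.9% T seen in B, and no value here separates them. No biological explanation was tested, as A and B carry the same genotype and antibody.

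Signal outside the lengths compared in the report made up 38.8% of RPM in the total pol IV table and 44.2% in the total dcl4 table, where 3 reads would be 0.604 and 0.238 RPM. Most of it was longer than 28 nt (29.2% and 40.4% of RPM). The leading tags of 33 nt were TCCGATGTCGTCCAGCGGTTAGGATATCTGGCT at 13991 RPM in pol IV and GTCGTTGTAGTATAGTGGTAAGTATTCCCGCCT at 62117 RPM in dcl4. The other 15 tables hold no lengths outside 18 to 28 nt, so no control is at hand.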

How the results depend on the processing

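The crossed block, the shared lengths of 16 and 20 nt, the count of tags present in another table and the list tests without AGO1-IP wild type B were chosen after seeing the data. Single-match tags, 500-bp windows and the removal of rRNA, tRNA, snRNA, snoRNA and organelle tags were not run, since they need a genome. The causes of the changes below were not tested, except where named.

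Calls between genotypes in AGO1-IP (19) became 0 with pseudocount 0.1, with a mean of at least 5 RPM, scaled to miRNA tags, under TMM and with edgeR, 1 with pseudocount 5 and at 22 nt alone, 3 at 21 nt alone, 675 with DESeq2 and 9163 without a filter, where 819311 tags are tested. AGO1-IP over mock-IP in wild type (0) became 5458 without a filter and 153 with DESeq2. In pol IV (1026) it became 1554 with pseudocount 0.1, 2 with pseudocount 5, 28 without a filter, 521 with a mean of at least 5 RPM, 0 scaled to miRNA tags and with edgeR, and 1 under TMM and at 22 nt alone. The difference of enrichment (0) became 19 without a filter. Leaving out each library gave 0 to 2126, 0 to 3200, 0 to 2457 and 0 to 1638 calls. Without either AGO1-IP pol IV library all were 0, and the highest came without AGO1-IP wild type A (2126 and 1638) or B (3200 and 2457). A lone library is then assumed to vary like the others.

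With the replicate letter as a block, the 4 comparisons gave 1, 0, 1 and 0 calls. The letters are not shown to pair libraries: the correlation of A minus B was −0.55 between AGO1-IP of the genotypes, 0.06 between AGO1-IP and mock-IP in wild type and −0.08 in pol IV. For Pol IV neighbourhoods between genotypes the camera call with an estimated correlation was lost under the block (adjusted p = 0.0942, against 0.0400). No other camera call of a list, with the preset or an estimated correlation, was changed by the block. Exchanging the letters in pol IV gave 105, 0, 1278 and 0 calls.

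The list call between genotypes was lost with an estimated correlation for conserved and nutrient-responsive miRNAs (adjusted p = 0.465 for both), and without AGO1-IP wild type B for the latter (0.0572). Neighbourhood sums of AGO1-IP over mock-IP reversed when scaled to miRNAs, to log2 −0.055 in wild type and −4.59 in pol IV. That scale divides by miRNAs that are themselves higher in AGO1-IP of wild type A and of pol IV. Over left-out libraries, these sums as deposited ranged from 0.90 to 2.38 and from 0.46 to 1.26. Between genotypes they ranged from −6.64 to −5.64 in AGO1-IP and from −6.11 to −4.67 in mock-IP. The T share of AGO1-IP minus mock-IP in wild type ran from −10.5 to 50.6 percentage points and reversed without A. The 21- to 22-nt share ran from 2.33 to 37.1.

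Among single tags in AGO1-IP over mock-IP of pol IV, scaled to miRNA tags, miR395a (−0.31), miR395b (−0.60), miR166 (−0.15) and miR164 (−0.21) reversed, as the scale is set by miRNAs. Over named tags and settings, the side of the threshold was kept in 750 cases between genotypes and 484 in AGO1-IP over mock-IP of pol IV. These counts include any change of direction where neither setting gave a call. A call was gained in 47 and 49 cases, and lost in 261 and 505.

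The 21- to 22-nt percent of wild type in neighbourhoods moved as follows. With a log2 drop of 3 it was 89.4 in dcl1, 27.8 in dcl2/dcl4, 1.73 in pol IV and 45.4 in dcl4. With at least 20 RPM it was 85.0 in dcl1, 26.0 in dcl2/dcl4, 65.8 in dcl2/dcl3/dcl4, 78.9 in rdr1, 2.03 in pol IV and 43.8 in dcl4. Scaled to miRNAs it was 39.8 in dcl2/dcl4, 74.1 in dcl2/dcl3/dcl4, 166 in rdr1, 1.14 in rdr1/rdr2/rdr6, 1.87 in pol IV and 118 in dcl4. In dcl1 it was 225, on a scale that the mutation itself lowers. A shared length of 16 nt gave 93.8 in dcl1, 29.8 in dcl2/dcl4 and 47.9 in dcl4, and 20 nt gave 90.1, 27.7 and 45.3, with 76.6 in rdr1. At 21 nt alone it was 65.5 in dcl1, 33.3 in dcl2/dcl4, 141 in dcl2/dcl3/dcl4, 74.8 in rdr1, 3.13 in rdr1/rdr2/rdr6, 2.99 in pol IV and 33.4 in dcl4. At 22 nt alone it was 107, 26.2, 21.8 and 76.7 in dcl1, dcl2/dcl4, dcl2/dcl3/dcl4 and rdr1, 1.35 in pol IV and 54.2 in dcl4. The 2 rdr1/rdr2/rdr6 libraries gave 1.46 and 2.67.

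Counts of tags against wild type moved by over 1.5 times when scaled to miRNAs: 192 higher in dcl2/dcl4, 40 lower and 331 higher in rdr1, 37 and 115 higher in rdr1/rdr2/rdr6, and 90 lower and 1327 higher in dcl4. In dcl1 that scaling gave 157 lower and 548 higher, in place of 243 and 98, but its mutation lowers the miRNAs that set the scale. Among tags present in another table, 232 were higher in pol IV and 144 in dcl4. Mock-IP pol IV A, with 203900 reads, sets 3 reads at 1.98 RPM, which limits what an AGO1-IP difference can show for rare tags.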

Other observations

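The tests of explanations in this part, the list of RDR- and DCL4-dependent tags and the copper relations were chosen after the results were seen.

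The 53 RDR- and DCL4-dependent tags, 42 of them of 21 nt, include TAS1 siR255 and TAS3 tasiR-ARF. They summed to 3187 RPM in total wild type and 3175 in pol IV, as their rule requires, and to 7.32% of wild type in dcl1 and 48.0% in rdr1, which the rule leaves free. The rdr1 value depends on the scale, as scaling to the listed miRNAs multiplies that library by 2.18. In the immunoprecipitations they reached 27322 RPM in AGO1-IP wild type A and 16111 and 34086 in AGO1-IP pol IV, against 299 to 410 in the 4 mock-IP libraries and 254 in AGO1-IP wild type B. In AGO1-IP wild type A 95.5% of their abundance began with T, against 63.7% in total wild type.

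AGO1-IP wild type A also held 24-nt tags that begin with T. They made up 93.6% of its 24-nt abundance, against 17.6% in AGO1-IP wild type B, 15.9% in total wild type and 18.6% and 18.8% in mock-IP. In pol IV they made up 63.1% and 84.0% of AGO1-IP and 18.2% and 19.9% of mock-IP. In Pol IV neighbourhoods the T share of 24-nt tags was 93.9% in AGO1-IP A, 15.2% in AGO1-IP B and 14.4% in total wild type. The 24-nt miR163 had 2090 RPM in AGO1-IP A, against 30.0 and 32.7 in mock-IP. The values for neighbourhoods rest on 1 library.

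The most abundant tag of the 4 mock-IP libraries was CCTTTGTCGCTAAGATTCGA. It took 43.6% and 33.0% of mock-IP pol IV, 18.7% and 10.9% of mock-IP wild type and 10.9% of AGO1-IP wild type B, but 1.67% of AGO1-IP wild type A and 0.126% of total wild type. GTTTGTTTGATGGTAACT took 1.84% to 3.47% of mock-IP libraries and 0.000955% of total wild type.

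Pol IV neighbourhoods kept 28.8% of 21- to 22-nt abundance in dcl2/dcl4 beside 88.4% of 23- to 24-nt abundance, which argues against shortened 24-nt siRNAs as the main source of the shorter tags. The scale of that library is argued against as the whole cause by the 21- to 22-nt abundance per 100 of 23 to 24 nt, 2.92 against 8.98 in wild type, which no scaling moves. For the 22-nt part, a hypothesis is that DCL2 makes most of it. In dcl2/dcl3/dcl4, a separate library, 22-nt tags stood at 21.8% of wild type. That value cannot isolate DCL2, since this mutant also lacks DCL3 and DCL4. In dcl4 22-nt tags stood at 54.2% as deposited and 137% when scaled to the listed miRNAs. Per 100 of 23 to 24 nt they were 6.92 in dcl4, 1.70 in dcl2/dcl4 and 5.72 in wild type. No dcl2 single mutant was analysed here, and each value is from 1 library.

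In dcl2/dcl3/dcl4 the 21-nt tags of Pol IV neighbourhoods stood above wild type, at 141%. Random breakdown is argued against by a 21-nt abundance of 5.03 times the mean of 20 and 22 nt, against 0.988 in wild type, and the scale by 160% when scaled to the listed miRNAs. A candidate explanation is that DCL1 takes over precursors that the other Dicer-like proteins leave. That was not tested, since no library analysed here lacks all 4.

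The copper-responsive miR398b, miR408 and miR397 varied together over the 9 total libraries. Over 6 relations, miR398b and miR408 had Pearson r = 0.963 (exact permutation p = 2.48e-05, adjusted 0.000149) and Spearman rho = 0.983 (exact permutation p = 4.96e-05, adjusted 0.000298). Without the 2 libraries farthest from the median of miR398b (dcl1 and dcl2/dcl4) r was 0.994. For miR397, r was 0.901 (exact permutation adjusted p = 0.00103) and rho 0.933. For miR857, also copper-responsive, r was 0.677 and did not pass (exact permutation adjusted p = 0.0640), with rho = 0.767 (exact permutation adjusted p = 0.0476). By contrast miR166 gave r = 0.225 (exact permutation adjusted p = 0.564), and miR827, of phosphate starvation, 0.544 (0.158). miR399b gave 0.750 (exact permutation adjusted p = 0.0394), but 0.493 without those 2 libraries. This may reflect copper supply or growth state of the plants behind each library rather than genotype. That hypothesis was drawn from r = 0.963 and is not tested by it. Genotype stays open beside it, since 7 of the 8 genotypes have 1 library. The 2 rdr1/rdr2/rdr6 libraries count separately among the 9.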
